A study of Homo sapiens with 6 samples.

How the data were processed

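The series holds 6 RNA-seq libraries of the human cell line AC16, 3 transfected with negative control siRNA and 3 with MLF1 siRNA. Groups and replicate numbers were taken from the sample titles, and each table column was matched to a sample through its title. The groups share no replicate number, so no pairing was used. Per the labels' protocols, total RNA was extracted with Trizol and libraries were prepared by the sequencing company's instructions. The extraction text names a cell type other than AC16, while the source, cell line and culture fields all give AC16, which is used here.

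Both deposited tables list the same 16911 genes, with an identifier and a symbol. The first holds estimated counts per gene made by the authors, not scaled between libraries. Between 84.1% and 84.5% of the values per library lie within 1e-06 of a whole number, and the rest have decimals, which is a property of expected-count estimates. The second holds FPKM values made by the authors, scaled by transcript length and sequencing depth. Per the submitters' processing notes, HISAT, Bowtie2 and the genome build GRCh38.p13 were used, with no role, order or version. The counting tool is not given in the sources used here, nor whether counting used strand, so overlapping genes, antisense genes and members of families with near-identical sequence are uncertain. Estimated counts divide shared reads between genes by a model, and this can shift values between such copies. No mitochondrially encoded mRNA is among the genes of the tables, so that list of 13 genes was not analysed here.

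The design foresaw whole-number counts. As the values are estimated counts, they were rounded to whole numbers first, and the tests were kept. Library totals ran from 16579466 to 17209211. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), library sizes were taken over the kept genes, and TMM factors ran from 0.991 to 1.01. The groups were compared with edgeR's quasi-likelihood F test (version 4.0.16, R 4.3.3) with group as the only term, and Benjamini-Hochberg adjusted p-values below 0.05 were called. Standard errors were derived from the log2 fold change and its F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD (n = 3). Unless another test is named, adjusted p-values are from this fit. At 7.71 CPM, the mean of MLF1 in siMLF1, the libraries hold 110 to 141 counts, so precision is lowest for genes at a few CPM.

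In all, 35 gene lists were fixed, and 33 had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. Of the 6 lists camera called, 3 upward and 3 downward, none held with an estimated correlation, where the smallest adjusted p over all lists was 0.21. The result of 1 tested list, not called by camera, is left out of the text. Fry, which does not compare a list with other genes, called 23. Symbols were matched through a table of Entrez identifiers where names differed. Genes named in the text are MLF1; tested members of the partner list; the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out LOC symbols; and members from the 4 with the smallest p in each list, of which not all are named. The tests, groups, lists, naming rule and most alternatives were fixed before the data were examined.

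The alternatives fixed at the outset were RLE, library size and upper-quartile scaling, DESeq2 (version 1.42.0), limma-voom, no filter or a stricter filter on low counts (at least 1 CPM in 3 libraries), limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5 or with no filter, a prior count of 0.5 for the lists, and leaving out each library in turn. A loess correction for GC content and transcript length, and list tests without genes holding AGAGGA or CGGAGA in the 3' UTR (minimum 3 members), were added after the data were seen. Those list tests also left out genes with no 3' UTR of at least 50 bases to search.

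For sequence features, 1 protein-coding transcript per gene (longest coding sequence, then longest transcript) was taken from GENCODE version 29 on GRCh38 through Entrez identifiers, which covered 13046 of 13192 tested genes (98.9%). Genes with a 3' UTR of at least 50 bases (12565) were searched. Word enrichment was a Mantel-Haenszel z of called against uncalled genes within strata of UTR length (20) or of length and GC content (10 each), compared with the largest z in each of 200 permutations within strata. In all, 8 searches were run, over both directions, both kinds of strata and log2 limits of 0 and 0.5, and 50 forms of both words with flanking bases were then examined.

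The steps were tested on simulated data. Counts were drawn for 13192 genes from the means, dispersions and library sizes of these libraries, with 200 genes changed and 1 further list shifted. For siMLF1 against siNeg, edgeR recovered 70% of the planted 1.25-fold changes, 88% of 1.5-fold, 92% of 2-fold and 100% of 4-fold changes. The limit first set for this test, more than 95% at 2-fold and at 4-fold each, was missed at 2-fold, where the genes not recovered had low counts, and it was restated after that for genes with a mean of at least 5 CPM. Of those, all 123 planted changes of at least 1.5-fold were recovered, against 17 of 27 below 5 CPM. Over 10 simulated draws, 6.92% of the genes called were unchanged ones (range 2.82% to 10.3%), somewhat above the nominal 5%. These draws changed 200 of 13192 genes, so that share does not carry over to the data, where 55.0% of genes were called. Nor did they test the scaling factors with so many genes changed.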

Results

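RNA was sequenced from cells of the human line AC16 after transfection with 1 of 2 siRNAs. These were a negative control siRNA (siNeg, 3 libraries, numbered 1 to 3) and an siRNA against MLF1 (siMLF1, 3 libraries, numbered 4 to 6). The medium was replaced 12 h after transfection. MLF1, myeloid leukemia factor 1, is an adaptor protein that binds 14-3-3 proteins and has been tied to cell cycle control through the COP9 signalosome. The comparison asks which transcripts differ in abundance when MLF1 is knocked down in these cells. The libraries held between 16579466 and 17209211 estimated counts over 16911 genes, and 13192 genes passed the filter on low counts and were tested. Correlations of log2 CPM (counts scaled to 1e+06 per library) ran from 0.994 to 0.996 between libraries of the same group and from 0.981 to 0.984 between libraries of different groups. The first principal component held 67.0% of the variance and separated siNeg from siMLF1. No pair of libraries differed by less than sampling noise, since the chi-square per degree of freedom was at least 1.81 in every same-group pair. It was 4.87 and 4.23 between siMLF1 6 and the other siMLF1 libraries, against at most 2.12 in the other same-group pairs, so siMLF1 6 stood apart from its group. Nothing in the labels ties the 3 libraries of a group to separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

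The MLF1 transcript fell in all 3 siMLF1 libraries. It stood at 33.1 ± 0.951 CPM (SD, n = 3) in siNeg and at 7.71 ± 0.945 CPM (SD, n = 3) in siMLF1, so that 23.3% of the control level remained. The estimated counts were 591, 558 and 554 in siNeg 1, 2 and 3 and 141, 135 and 110 in siMLF1 4, 5 and 6. The log2 fold change was -2.10 ± 0.08 (SE), with an adjusted p of 1.41e-13 in edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. In the authors' FPKM table the group means were 18.9 and 4.53. MLF1 (gene identifier 4291) lies on the plus strand of chromosome 3, where the transcript used here spans positions 158582835 to 158606459 of GRCh38 in the GENCODE annotation. That transcript is 2157 bases long, with a coding sequence of 897 bases and a 3' UTR of 1257 bases.

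**Figure D1:**
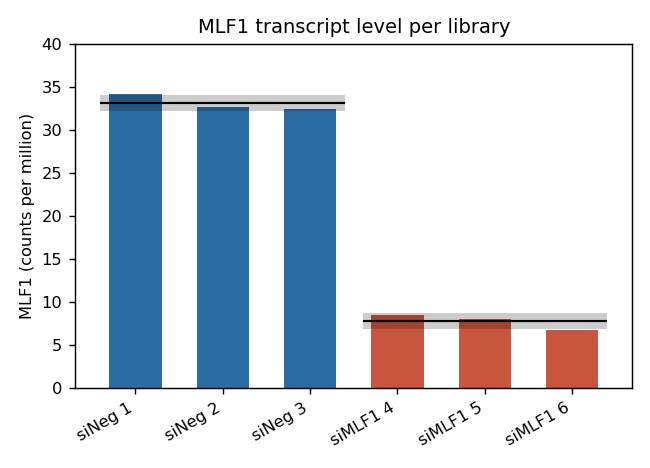
MLF1 level in CPM for each library, with the group mean as a line and ±1 SD as a grey band (n = 3 per group). Every siMLF1 library lay at or below 8.47 CPM and every siNeg library at or above 32.5 CPM.

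Beyond MLF1, a large share of the tested genes differed between the groups, mainly by small amounts. Of the 13192 tested genes, 7258 (55.0%) passed an adjusted p of 0.05, and they divided into 3620 that rose and 3638 that fell in siMLF1. The median absolute log2 fold change of the genes that passed was 0.31. The larger changes were mostly decreases: 997 genes fell and 350 rose by at least 1.5-fold, and 338 fell and 54 rose by at least 2-fold. In 7949 genes (60.3%) all 3 libraries of one group lay above all 3 of the other, against the 10% that chance would give. The small spread between libraries, a biological coefficient of variation of 3.65%, let small differences pass the test. The count at 2-fold or more depended on the scale: 392 genes reached it on the counts, and 66 on log2(FPKM + 1), a scale that compresses the changes of weakly expressed genes.

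**Figure D2:**
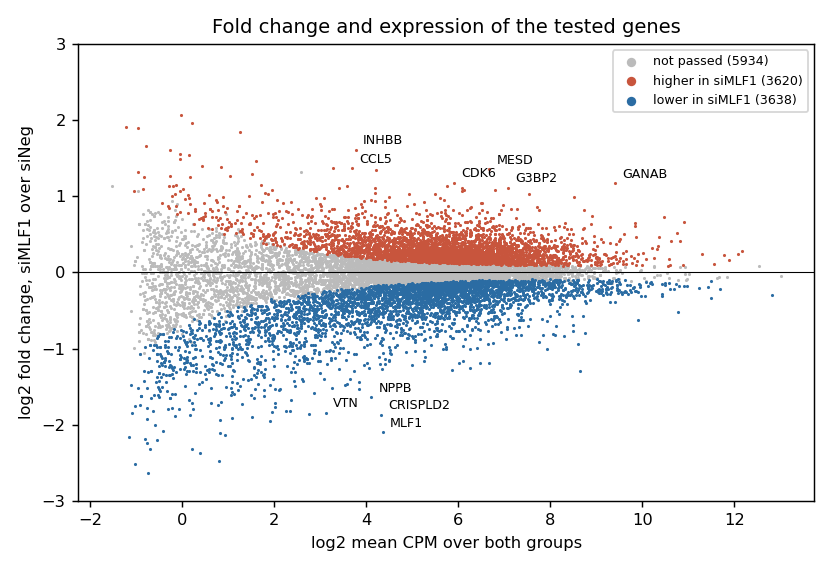
Log2 fold change of siMLF1 over siNeg against log2 mean CPM for the tested genes, with genes that rose (3620) and fell (3638) at an adjusted p below 0.05 in colour and the others in grey. The points below -1 outnumber those above 1, and 1 gene lies outside the plotted range of ±3.

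Among genes of at least 5 CPM, the 11 largest decreases after MLF1 included genes of several secreted proteins and of intracellular ones. CRISPLD2, a secreted glycoprotein, fell from 31.4 ± 0.841 to 8.59 ± 0.307 CPM (log2 fold change -1.87 ± 0.07, adjusted p = 1.41e-13). VTN, which encodes the adhesive plasma protein vitronectin, changed by -1.84 ± 0.11, and FMOD, the collagen-binding proteoglycan fibromodulin, by -1.83 ± 0.19. The serine protease gene HTRA3 changed by -1.82 ± 0.15, the C1q-related C1QTNF1 by -1.67 ± 0.15 and the growth factor FGF18 by -1.62 ± 0.17. NPPB, the gene for the cardiac natriuretic peptide BNP, fell from 26.0 ± 1.49 to 8.33 ± 0.798 CPM (-1.64 ± 0.09, adjusted p = 5.04e-12). The remaining genes of this set were the globin CYGB (-1.86), the mTOR inhibitor DEPTOR (-1.82), ARHGEF16 (-1.76) and DACT3 (-1.71).

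The largest increases included INHBB, the inhibin and activin beta B subunit, which rose from 6.71 ± 1.07 to 20.5 ± 0.858 CPM (log2 fold change 1.61 ± 0.10, adjusted p = 5.19e-11). The chemokine CCL5 rose by 1.37 ± 0.09 and the antiviral enzyme OAS2 by 1.37 ± 0.12. Several well expressed genes were in this set. MESD, an ER chaperone, rose from 57.4 ± 0.457 to 147 ± 4.23 CPM (1.35 ± 0.04), and GANAB, the catalytic subunit of ER glucosidase II, rose from 417 ± 9.05 to 939 ± 13.9 CPM (1.17 ± 0.04), both with an adjusted p of 5.56e-15. The cyclin-dependent kinase gene CDK6 rose by 1.18 ± 0.05 and the stress granule gene G3BP2 by 1.11 ± 0.05. CCDC85A (1.35), SFT2D3 (1.14), BICD2 (1.13), the histone gene H2BC21 (1.11) and IFIT2 (1.11) completed the set. H2BC21 belongs to a multigene family of near-identical coding sequences, so its value is uncertain.

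Genes of the endoplasmic reticulum (ER) folding machinery, interferon-stimulated genes and proteasome subunits were higher in siMLF1 as groups by camera with a preset correlation, though not with an estimated one. Of 22 tested ER chaperone and unfolded protein response genes, 17 rose, 2 fell and 3 did not pass, with a median log2 fold change of 0.42. The chaperone gene HSPA5 rose from 711 ± 10.8 CPM by 0.65 ± 0.04, and HYOU1 (0.56), PDIA3 (0.47) and the transcription factor gene XBP1 (0.58) also rose. Of 38 interferon-stimulated genes, 26 rose, 3 fell and 9 did not pass (median 0.27), among them OASL (0.93 ± 0.09) and IFIT1 (0.51 ± 0.06). Of 32 proteasome subunit genes, 17 rose, 1 fell and 14 did not pass (median 0.12), led by PSMD11 (0.46 ± 0.04), with PSMC3 at 0.31 and PSMD2 at 0.22. These counts were the same when adjusted over the list alone. By limma's camera with a preset correlation, the adjusted p was 3.20e-05 for the ER list, 0.000197 for the interferon list and 0.0137 for the proteasome list. None of the 3 calls held when the correlation was estimated from the data: adjusted p = 0.21 with an estimated correlation for the ER list, 0.596 for the interferon list and 0.721 for the proteasome list. The proteasome call was also lost without siMLF1 4 (adjusted p = 0.0671, in a range from 0.000495 to 0.721 over the alternatives).

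Genes of hypoxia and glycolysis and of cytosolic ribosomal proteins were lower in siMLF1 as groups by camera with a preset correlation, though not with an estimated one. Nuclear-encoded oxidative phosphorylation genes leaned lower, a call that was lost in 5 of 15 alternatives. In the hypoxia and glycolysis list, 25 of 35 tested genes fell, 1 rose and 9 did not pass (median -0.19), or 26 lower and 2 higher when adjusted over the list alone. The mitophagy receptor gene BNIP3 changed by -0.82 ± 0.05, the carbonic anhydrase gene CA9 by -1.16 ± 0.07, LDHA, which encodes a lactate dehydrogenase subunit, by -0.51 ± 0.04 and ALDOC by -0.54 ± 0.05. Of 78 ribosomal protein genes, 62 fell, 1 rose and 15 did not pass (median -0.19), or 65 lower and 1 higher when adjusted over the list alone. The changes were small, such as -0.38 ± 0.05 for RPL27A, -0.28 ± 0.04 for RPL3 and for RPS3A and -0.25 ± 0.04 for RPL7. Ribosomal protein genes have many processed pseudogenes with which they can share reads. Of 71 oxidative phosphorylation genes, 34 fell, 5 rose and 32 did not pass (median -0.11), or 34 lower and 6 higher when adjusted over the list alone. SDHD (-0.74 ± 0.06), COX5B (-0.49 ± 0.05) and UQCRB (-0.36 ± 0.04) were among those that fell. Camera's adjusted p was 0.000121, 1.35e-06 and 0.0331 for the hypoxia, ribosomal and oxidative phosphorylation lists, against adjusted p = 0.596, 0.721 and 0.858 with an estimated correlation. The ribosomal call was lost by fry (adjusted p = 0.0542). The oxidative phosphorylation call was lost by fry (adjusted p = 0.212). By camera it was lost without siNeg 1 (adjusted p = 0.0697) and without siMLF1 6 (0.182, with the median at -0.05). It was also lost by camera after a correction for GC content and transcript length (adjusted p = 0.0987, with the median at -0.06). Its adjusted p ranged from 0.00272 to 0.858 over the alternatives. In siMLF1 6, ribosomal protein genes took 4.68% of the counts, against 5.25% and 5.32% in the other siMLF1 libraries and 5.72% to 5.92% in siNeg. Without siMLF1 6 the ribosomal median was -0.13.

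**Figure D3:**
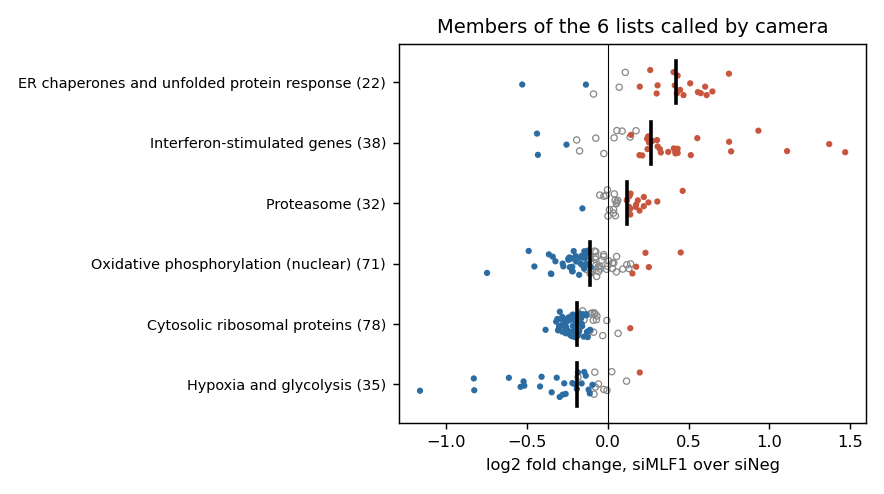
Log2 fold change of each tested member of the 6 lists that passed camera's test with a preset correlation, with the number of members in brackets. Filled points passed an adjusted p of 0.05 (red higher, blue lower in siMLF1), open points did not, and the bar marks the list median, from 0.42 for the ER list to -0.19 for the hypoxia list.

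Several known partners of MLF1 and regulators tied to it changed modestly. Of 10 tested partner genes, 6 rose, among them the ubiquitin ligase gene MDM2 (0.43 ± 0.05), COPS3 (0.20 ± 0.04), MLF2 (0.20 ± 0.04), the 14-3-3 gene YWHAZ (0.17 ± 0.04) and NRBP1 (0.13 ± 0.04). HAX1, an anti-apoptotic mitochondrial protein gene, fell (-0.27 ± 0.05). COP1 (0.08 ± 0.06), CENPU (-0.08 ± 0.04) and DNAJB6 (0.03 ± 0.04) did not pass. The adjusted counts over the list alone were the same, and camera's adjusted p was 0.167. Of 10 COP9 signalosome subunit genes, 4 rose, none fell and 6 did not pass, with COPS2 at 0.25 ± 0.04, COPS4 at 0.17 ± 0.05 and COPS7B at 0.14 ± 0.05, and the same counts when adjusted over the list alone (camera adjusted p = 0.242).

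The cell cycle and apoptosis lists moved in both directions. Of 47 G1/S and DNA replication genes, 8 rose and 20 fell, the latter including the helicase gene MCM6 (-0.45 ± 0.04) and the DNA ligase gene LIG1 (-0.34 ± 0.04). Of 48 G2/M and mitosis genes, 11 rose and 17 fell (18 when adjusted over the list alone). CKS1B (-0.56 ± 0.04) and the phosphatase gene CDC25B (-0.46 ± 0.04) fell, and the checkpoint kinase gene BUB1 rose (0.40 ± 0.04). Of 28 apoptosis regulators, 10 rose and 8 fell (9 when adjusted over the list alone). The pro-apoptotic genes BMF (-1.05 ± 0.07) and BID (-0.58 ± 0.07) and the anti-apoptotic MCL1 (-0.36 ± 0.04) fell, while CYCS, cytochrome c, rose (0.45 ± 0.04). The median and the mean of the apoptosis list differed in sign (0.07 and -0.01). The counts adjusted over the list alone were otherwise the same, and camera's adjusted p was 0.136 for G1/S, 0.684 for G2/M and 0.806 for apoptosis.

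Cardiac genes were sparsely expressed, and those measured went both ways. Of the 6 sarcomere genes that could be tested, TPM1 (-0.30 ± 0.04), DES (-0.65 ± 0.14) and ANKRD1 (-0.87 ± 0.18) were among the 4 that fell, and MYPN rose (0.42 ± 0.08). Of 14 cardiac transcription factor and ion handling genes, 3 rose and 6 fell. They included ATP2A2, the sarcoplasmic reticulum calcium pump (0.24 ± 0.04), MEF2A (-0.28 ± 0.05), MEF2D (-0.30 ± 0.05) and NPPB. Neither list passed camera's test (adjusted p = 0.242 for both), and the counts adjusted over the list alone were the same.

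Extracellular matrix genes, collagens among them, changed in both directions. Of 40 extracellular matrix genes, 21 rose and 13 fell (14 when adjusted over the list alone), and camera's adjusted p was 0.221. COL4A1 rose from 243 ± 4.47 to 483 ± 21.9 CPM, COL1A2 by 0.73 ± 0.04 and COL3A1 by 0.67 ± 0.04, and the fibulin gene FBLN1 fell (-0.97 ± 0.06). Of 27 TGF-beta response genes, 8 rose and 10 fell, with the receptor gene TGFBR2 at -0.94 ± 0.06, TGFBI at -0.77 ± 0.04, PMEPA1 at -1.49 ± 0.15 and LTBP1 at 0.77 ± 0.08 (camera adjusted p = 0.569). Of 23 YAP/TEAD targets, 9 rose and 7 fell (8 when adjusted over the list alone), with the receptor kinase gene AXL at 0.61 ± 0.04, LATS2 at 0.86 ± 0.06 and ARHGEF17 at -0.52 ± 0.04. That list's median was -0.04, its mean 0.01 and its camera direction upward (adjusted p = 0.926).

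Cell type marker genes differed between lists, with rises and falls in some and only falls in others. Of 15 fibroblast markers, 8 rose and 5 fell, with LUM at 0.34 ± 0.04 and FAP at 0.29 ± 0.04 beside the collagens; the median (0.16) and mean (-0.02) of this list differed in sign. Of 10 smooth muscle markers, 4 rose, including TAGLN (0.23 ± 0.04), and 5 fell, including CALD1 (-0.28 ± 0.04). Of 8 endothelial markers, 5 fell and none rose (median -0.53), with EGFL7 at -0.62 ± 0.08 and FLT1 at -0.64 ± 0.17, the latter from 3.97 ± 0.119 CPM, and KDR at -0.42 ± 0.15. Epithelial markers (1 of 9 higher and 1 lower) and neuronal markers (none of 5 higher and 2 lower) changed little in number, with KRT19 at 0.36 ± 0.09, SNAP25 at -0.60 ± 0.08 and SYP at -1.13 ± 0.35, and with KRT17 (-0.16 ± 0.10), KRT18 (0.06 ± 0.04) and SYN1 (-0.16 ± 0.39) among those that did not pass. The calls of COPS4, COPS7B, KDR and SYP were lost in at least 1 alternative each. The counts adjusted over the list alone were the same in all 5 lists. Camera's adjusted p was 0.242 for fibroblast, 0.806 for smooth muscle, 0.0557 for endothelial, 0.985 for epithelial and 0.569 for neuronal markers. Among leukocyte and erythroid markers 4 genes were tested, too few for a list test, and of these CD14 fell (-1.11 ± 0.13), while CD68 (0.10 ± 0.05) and PTPRC (-0.79 ± 0.43) did not pass.

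Inflammatory and stress response genes also changed without passing camera's test. Of 24 NF-kB and inflammatory cytokine genes, 9 fell and 2 rose (9 and 1 when adjusted over the list alone). CSF1 (-0.91 ± 0.07) and IL1B (-1.12 ± 0.13) fell and SOD2, the mitochondrial superoxide dismutase, rose (0.33 ± 0.04), with a camera adjusted p of 0.0565. Of 20 heat shock genes, 10 rose, including HSP90AA1 (0.34 ± 0.04) and HSPD1 (0.33 ± 0.04), and 2 fell (adjusted p = 0.0784). HSPA1B (-0.25 ± 0.04) shares most of its sequence with HSPA1A, so its value is uncertain. Of 35 ATF4 and amino acid response genes, 14 rose and 7 fell. The alanyl-tRNA synthetase gene AARS1 rose (0.35 ± 0.04), and the amino acid transporter genes SLC1A5 (-0.62 ± 0.04) and SLC7A5 (-0.29 ± 0.04) fell (adjusted p = 0.221). Of 21 NRF2 targets, 10 fell, including HMOX1 (-0.36 ± 0.06) and GCLM (-0.35 ± 0.06), and 2 rose, including ME1 (0.62 ± 0.06; adjusted p = 0.242). Of 25 immediate early genes, 8 rose and 8 fell, with FOSL1 at 0.65 ± 0.06 and DUSP4 at -0.96 ± 0.08. That list's median (-0.01) and mean (-0.05) were below 0 while its camera direction was upward (adjusted p = 0.989). The counts adjusted over the list alone were the same for these last 4 lists.

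Metabolic, signalling and RNA interference genes also changed in both directions. Of 25 cholesterol synthesis genes, 11 rose and 6 fell, with CYP51A1 at 0.38 ± 0.05. Of 25 fatty acid oxidation genes, 9 rose (10 when adjusted over the list alone) and 6 fell, with CPT1B at -0.51 ± 0.07 and CPT2 at 0.29 ± 0.05. Of 36 autophagy and lysosome genes, 12 rose and 11 fell (12 when adjusted over the list alone), with ATG5 at -0.39 ± 0.05. The medians of the fatty acid (-0.01) and autophagy (-0.02) lists lay below 0 while camera's direction was upward, and the mean of the autophagy list lay above 0 (0.000736) and that of the fatty acid list below it (-0.04). Of 19 Wnt genes, 4 rose and 8 fell, with the cyclin gene CCND1 at -1.44 ± 0.10 and the Wnt inhibitor gene DKK1 at -0.42 ± 0.06. Of 15 Notch genes, 3 rose and 8 fell (9 when adjusted over the list alone), with NOTCH1 at -0.45 ± 0.06 and its ligand gene JAG1 at -0.75 ± 0.12. Of 13 RNA interference genes, 6 rose and 1 fell: DROSHA, the microRNA processing nuclease, was at 0.50 ± 0.04 and TNRC6A at -0.46 ± 0.04. The other counts were the same when adjusted over the list alone. Camera's adjusted p was 0.242 for cholesterol synthesis, 0.985 for fatty acid oxidation, 0.926 for autophagy, 0.136 for Wnt, 0.072 for Notch and 0.242 for RNA interference.

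Fold changes also differed by short sequences in the 3' UTR, which were examined because an siRNA can act on transcripts that match its seed. The 3' UTRs of 12565 tested genes were searched for every 6-base word. Among genes lower in siMLF1, AGAGGA was the most enriched word against unchanged genes of like UTR length and GC content (z = 9.17, with the 95th percentile of the largest permuted z at 4.25). Among genes higher in siMLF1 it was CGGAGA (z = 5.44, against 4.38). The 4779 genes with AGAGGA in the 3' UTR had a median log2 fold change of -0.03 (95% bootstrap interval -0.04 to -0.01), and 1532 (32.1%) of them fell, against 1950 of the 7786 genes without it there. The 994 genes with CGGAGA had a median of 0.06 (0.03 to 0.08), and 37.4% of them rose, against 26.8% of genes without it there. Both words were found in the same genes that these medians describe. The intervals come from resampling genes, which are not independent replicates, and hold no spread between libraries. In all, 50 forms with flanking bases were examined after that. Among the 7-base forms, AGAGGAA (2358 genes) had the lowest median, -0.06, and CGGAGAA (280 genes) the highest, 0.15. Among the 8-base forms, the medians were lowest for AAGAGGAA (861 genes) and TAGAGGAA (502 genes), both -0.08. The highest was TCGGAGAA (65 genes), at 0.20. All of these were picked for their size. Among the largest falls after MLF1, AGAGGA was found in CRISPLD2, FMOD, DEPTOR, HTRA3, DACT3, C1QTNF1 and FGF18. It was not found in VTN, ARHGEF16 or NPPB, and CYGB was not searched. Among the largest rises, CGGAGA was found in INHBB, MESD, CDK6, SFT2D3, BICD2 and G3BP2. It was not found in CCL5, OAS2, CCDC85A, GANAB, H2BC21 or IFIT2. AGAGGA was also found in the rising INHBB, MESD, CDK6, BICD2 and H2BC21, and CGGAGA in the falling CRISPLD2 and FMOD. By camera with the preset correlation, all 6 list calls held without genes that had either word in the 3' UTR or were not searched. The adjusted p ran from 3.04e-05 for ribosomal proteins, with 45 of 78 genes kept, to 0.044 for oxidative phosphorylation. In that test the G1/S list (adjusted p = 0.0284, lower) and the ATF4 list (0.0235, higher) passed as well. With all members and an estimated correlation, the adjusted p was 0.721 for G1/S and 0.596 for ATF4, and none of the 6 calls held.

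**Figure D4:**
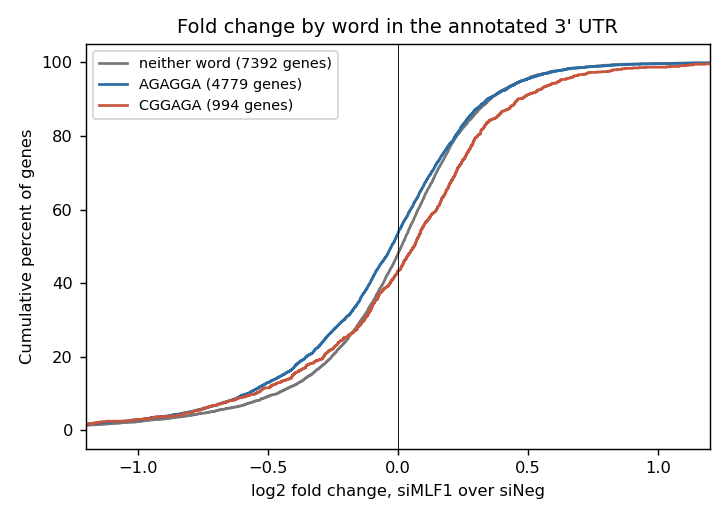
Cumulative percent of searched genes by log2 fold change of siMLF1 over siNeg, for genes whose 3' UTR holds AGAGGA (4779 genes, median -0.03), CGGAGA (994 genes, median 0.06) or neither (7392 genes, median 0.01). Genes holding both words are in both coloured curves.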

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

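The correction for GC content and transcript length and the list tests without genes holding either 3' UTR word were chosen after the data were seen; the other alternatives were planned. The number of changed genes ran from 5988 (DESeq2) to 7668 (GC and length correction), and from 6289 to 7230 with 1 library left out. In each of these 17 settings, every gene called there and in the reported fit had the same direction. The MLF1 log2 fold change ran from -1.86 to -2.17. Upper-quartile factors gave 3090 higher and 4074 lower genes (43.1% higher, against 49.9%), and moved the median of all genes to -0.03. The count at 2-fold or more was 66 on log2(FPKM + 1) and 65 with no filter, against 392; the pseudocount compresses low values, and 270 genes passed with a pseudocount of 0.1. The number of lists called was 0 with an estimated correlation, 23 by fry, which asks another question, and 10 with no filter on low counts, against 6; the cause of the last was not tested. It was 8 with a stricter filter and 5 to 8 with 1 library left out. Calls of lists were gained 27 times over the other settings and 9 times with a library left out, the latter for NF-kB, endothelial and Notch genes. The interferon, ER and hypoxia calls held in 14 of 15 settings each, all but the estimated correlation. The ribosomal call was also lost by fry (adjusted p = 0.0542), the proteasome call without siMLF1 4, and the oxidative phosphorylation call in 5 settings in all. Among lists, direction reversed only in some far from the threshold, by camera's or fry's direction; the cause was not tested. The medians there were 0.0101 for G2/M without the word genes; -0.0184 with a stricter filter and -0.149 without the word genes for immediate early genes; -0.00946 by fry, -0.016 with a stricter filter and -0.0286 with no filter for fatty acid oxidation; and 0.0655 after the GC and length correction for epithelial markers. With 1 library left out, medians ran from -0.0657 to -0.00742 for YAP/TEAD targets, from -0.0648 to -0.00189 for immediate early genes, from -0.0374 to -0.00183 for fatty acid oxidation and from -0.037 to 0.025 for epithelial markers. Over the 158 genes that the naming rule allowed, calls were lost with the direction kept 7 times with a library left out and 7 times otherwise: COPS4 without siNeg 3, SYP without siMLF1 5, and COPS7B and KDR in 6 settings each. Calls were gained 4 times with a library left out and 6 times otherwise, for CENPU, CD68, KRT17, KRT18 and PTPRC. SYN1, at 0.760 CPM in siNeg and not called, changed direction 2 times, with log2 fold changes from -0.649 to 0.144 with 1 library left out.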

Other observations

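The direct-match tests for AGAGGA and CGGAGA, the GC and length tests of the lower genes and of the ZNF-named genes, the search for flanking bases, the scan of 7 words in ZNF-named genes and the comparisons of gene families were chosen after the results were seen.

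Some gene families outside the fixed lists held more genes that rose than fell; they were picked from the data, with no set test. Of 466 tested genes with a ZNF number as their name, mostly zinc finger transcription factors, 182 rose and 33 fell, with a median log2 fold change of 0.19. In the protocadherin beta cluster, which encodes neural cell adhesion proteins, 7 of 9 tested genes rose and none fell (median 0.95), and in the gamma cluster 9 of 18 rose and 1 fell (median 0.46). Their median siNeg levels were low, at 1.13 CPM for beta and 2.55 CPM for gamma, against 33.7 CPM over all tested genes. Of 16 replication-cluster histone genes, 9 rose and none fell, with a median of 1.07 at a median siNeg level of 0.768 CPM; these near-identical genes can share reads. Single-exon protein-coding genes as a class had a median of 0.14, with 91 of 253 higher and 38 lower, against -0.00 for genes with several exons. In 174 single-exon genes with at most 5 counts over siNeg, summed counts were 276 in siNeg and 323 in siMLF1, a ratio of 1.17, against 0.987 for the 1852 such genes with several exons. This comparison was first made as a test for genomic DNA after the result was seen, picked genes by low counts in siNeg alone, and is not weighed here.

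The real division of the 6 libraries gave 7258 changed genes and the highest of the other divisions into 3 and 3 gave 0, so 1 of the 10 divisions reached the real value. With 10 divisions no share below 0.05 can be had. A wrong label would put an siMLF1 library among the controls for MLF1, but the highest siMLF1 library stood at 8.47 CPM against 32.46 CPM in the lowest siNeg library. The correlation across genes between log2 fold change and transcript length was 0.104. This lay between the limits of 0.1 and 0.2 set before the test, so a part played by length cannot be told apart. The correlation with transcript GC content was larger, at -0.182, and no limit had been set for it. Genes are not independent replicates.

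The genes lower in siMLF1 are the first pattern, and off-target action of the MLF1 siRNA through its seed may account for part of it. Searches whose predictions were written before they were run gave AGAGGA as the most enriched word at z = 10.42 with UTR length matched (limit 4.17), where 188 words passed, and at z = 9.17 with GC content matched too (limit 4.25), where 3 overlapping words passed. AGAGGA occurs in the MLF1 coding sequence at transcript position 211, although 32.8% of all 6-base words occur somewhere in that transcript. The longer form TAGAGGA occurs there at position 210, and 11.04% of all 7-base words occur somewhere in the transcript. The longer forms AGAGGAA and TAGAGGAA are absent from it. The siRNA sequence was not used here. A match in the 3' UTR is not the whole source, since 56.0% of searched lower genes (Wilson interval 54.4% to 57.6%) hold no AGAGGA there. As 4779 of all 12565 searched genes hold it there, a large share without it was set in advance. The excess over word-free genes of like length and GC content was 506 genes, or 14.5% of the lower genes searched. Matches elsewhere were not weighed. Of the 5100 genes with AGAGGA only in the 5' UTR or coding sequence, 26.4% fell, against 22.45% of the 2686 with none. Those sets were not matched for length. A GC and length trend is not the whole source either, as its removal left 3731 lower genes against 3638. Of 7668 genes called after it, 6773 were also called before, all in the same direction. Indirect effects, other off-target routes and a response to the loss of MLF1 stay open and untested.

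The genes higher in siMLF1 are the second pattern. If the control siRNA lowered its own off-targets, these would look higher in siMLF1. The most enriched word was CGGAGA (z = 5.44, limit 4.38), which leaves this a candidate explanation for a small part. CGGAGA is absent from the MLF1 transcript. Only 32.8% of all 6-base words occur there, so the absence does not weigh for or against this candidate. CGGAGA led in all 4 searches of higher genes, as AGAGGA did in all 4 of lower genes. The searches of a direction share their genes, since the set at a log2 limit of 0.5 lies within that at 0. They are therefore not separate support. A 3' UTR match cannot account for most higher genes: 89.3% of those searched (Wilson interval 88.2% to 90.3%) hold no CGGAGA there. As 994 of all 12565 searched genes hold it there, a large share without it was set in advance. The excess was 92.4 genes, or 2.66%. Matches elsewhere in the transcript were not weighed for this pattern. Of the 4392 genes with CGGAGA only in the 5' UTR or coding sequence, 30.8% rose, against 24.45% of the 7179 with none. Those sets were not matched for length. Neither siRNA sequence was used here, and a response to the loss of MLF1 stays open and untested.

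The rise of ZNF-named genes is the last pattern. Exact CGGAGA matches were argued against: the 241 genes with none in the transcript had a median of 0.184 (95% bootstrap interval 0.145 to 0.217), close to the 0.185 of all 462 with a transcript, and the correlation with the number of matches outside the 3' UTR was 0.047 (permutation p = 0.296). A GC and length trend was argued against as well, as the corrected median was 0.176 (0.139 to 0.202). Both intervals come from resampling genes and hold no spread between libraries. Of the 7 words scanned, however, TGGAGA, which differs from CGGAGA in its first base, did correlate with the fold change across genes (rho = 0.273, adjusted permutation p = 7e-05, from the smallest p the permutations can give). The number of TGGAGA also follows the number of finger linker motifs (rho = 0.724). Some forms of the counted motif contain TGGAGA itself, so that correlation is partly built in. Inexact seed pairing and a property of genes with many fingers may each underlie the correlation with the fold change. They were not separated, and a biological response stays open.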
